A study of Mus musculus with 14 samples.

How the data were processed

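RNA was measured in follicular B cells isolated from mouse spleen with a magnetic bead kit and cultured with BAFF at 50 ng per ml. Per the labels, RNA was purified on columns, reverse transcribed from poly-dT and sequenced on Illumina libraries, and the 14 libraries fall into 7 groups of 2: wt at 0h, 6h and 27h, and cko and dbko at 0h and 6h. The deposited values are counts of reads per Ensembl gene ID, whole numbers with no normalization, with 1 table per library and nothing pooled. The submitters' processing notes name CASAVA 1.8.2, and the aligner, the counting tool, the genome build, the annotation and the use of strand are not given in the sources used here. Each table ends with tallies of reads outside genes. Of all reads tallied, 5.21 to 11.46% per library lay in no feature, 38.77 to 49.85% aligned to more than 1 place and 0.41 to 0.49% were ambiguous, and the tally of unaligned reads was 0, so these tables do not show how many reads failed to align. Since reads with more than 1 place are outside the gene counts, values of genes with near copies (the alpha and beta globins, Hspa1a and Hspa1b, Bcl2a1b, the Ifi200 family, Hmgn2 and the H2 genes) are uncertain.

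Gene counts summed to 10497802 to 11888765 per library, with 15438 to 16490 genes counted at least once, 4.05 to 6.94% of the counts in the 10 most abundant genes and 1.58 to 2.89% in the mitochondrial genome. Gene IDs were matched to symbols and positions in GENCODE M21 on GRCm38, which may not be the build the authors used: 37607 of 39179 IDs matched, with 99.54% of the gene counts. Replicate numbers follow the sequencing lanes, replicate 1 in lane 7 and replicate 2 in lane 8.

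Counts were scaled by TMM in edgeR 4.0.16 (R 4.3.3, limma 3.58.1), and 12630 genes passed filterByExpr by group. A quasi-likelihood model (glmQLFit, robust) with 1 mean per group was fitted to all 14 libraries, with 7 residual degrees of freedom and a common biological coefficient of variation of 0.144, and contrasts were tested with glmQLFTest, two-sided. P-values were adjusted by Benjamini and Hochberg over the genes tested in a comparison, and a gene was called at an adjusted p under 0.05. A difference of 6h responses was tested as the difference of the 6h minus 0h differences of 2 genotypes. Levels are CPM on TMM-scaled library sizes, and average log2 CPM used a prior count of 2. Principal components used log2 of CPM plus 1 on unscaled library totals, with genes of low mean count left out. Other values were computed with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.

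Before the data were examined, 40 gene lists were fixed. They cover Rel and Relb with their neighbours, NF-kB subunits and targets, survival and apoptosis, BAFF receptors and ligands, stages and subsets of B cells, other cells of the spleen, cell cycle, growth and metabolism, stress, interferon, immediate early, antigen presentation, migration and receptor signalling genes, and sex-specific, mitochondrial, immunoglobulin and reference genes. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, and p-values were adjusted over the lists within a comparison. Of 476 tests of a list in a comparison 190 were called, and with a correlation estimated from the data 9 of them held. These were immediate early and migration genes in wt at 27h against 0h, heat shock genes in cko at 6h against 0h, in cko against wt at 0h and in dbko against cko at 0h, erythroid markers in dbko against wt and against cko at 0h and against cko at 6h, and B-1 markers in dbko against cko at 6h. With fry, which tests whether members move one way and compares them with no other genes, 129 of the 190 were called.

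Genes to be named were also fixed beforehand. They are Rel and Relb, and for each comparison the 8 called genes with the largest rise and the 8 with the largest fall among those with an average log2 CPM of at least 3 and a proper symbol. From each list came up to 4 called members with the smallest adjusted p, and every member of the shortest lists. From these the report takes mainly genes whose call held with any 1 library of the groups compared left out, and gives the adjusted p without each deciding library for the others. Where a compared group lay near 0, levels are given instead of fold changes. Results of 4 genes that the rule names are not reported here.

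Alternatives planned beforehand were DESeq2 size factors in edgeR, no filter on low counts, DESeq2 1.42.0, the replicate number as a block, a fit of the compared groups alone, and leaving out each library in turn, in which a lone library is assumed to vary like the other groups. Chosen after seeing the data were a replicate block within each genotype and leaving out the first or the second dbko replicate at both times. Whether replicate numbers pair libraries across groups was checked by correlating deviations from group means across genes: of 21 pairs of groups 5 had a correlation over 0.1, with a range of -0.268 to 0.483. The method was tested on simulated data, negative binomial counts with the mean of each gene over the libraries, its fitted dispersion and the real library sizes, in which 200 genes were changed in wt at 6h. Calls were made for 7 of 63 genes changed 1.5-fold, 45 of 65 changed 2-fold and 53 of 64 changed 4-fold, and 5 unchanged genes were called. With 0 genes changed in cko at 6h against 0h, edgeR called 0 genes, and 4.58% had an unadjusted p under 0.05.

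Groups of 2 allow neither a test for an outlying library nor a count of other splits of the samples. The lists of sex-specific, natural killer, neutrophil, stromal and BAFF receptor genes had fewer than 5 tested members and so have no list test.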

Results

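RNA-seq counts were obtained from follicular B cells, the recirculating mature B cells of the spleen, of C57BL/6 mice with 3 genotypes: wild type (wt), lacking c-Rel (cko), and lacking both RelB and c-Rel (dbko). RelB and c-Rel are subunits of the transcription factor family NF-kB, encoded by Relb and Rel. The cells were cultured with 50 ng per ml of BAFF, the cytokine that keeps mature B cells alive, for 0h or 6h in each genotype and for 27h in wt alone. Each of the 7 groups held 2 libraries, n = 2. The series asks how RelB and c-Rel act together in the survival and development of B cells. Values are log2 fold changes ± SE from the edgeR model, with adjusted p-values, and levels are given as CPM, counts scaled by library size, of replicate 1 and replicate 2. Nothing in the labels says that the 2 libraries of a group came from separate animals, so the p-values measure only the spread between these libraries.

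Rel was low in both knockouts and Relb was reduced, but not absent, in dbko. Rel (ENSMUSG00000020275, chromosome 11, 23736847 to 23770970, minus strand, in GRCm38) stood at 633 and 620 CPM in wt at 0h, 672 and 683 CPM at 6h and 196 and 198 CPM at 27h. In cko it stood at 58.3 and 52.4 CPM at 0h and 111 and 95.2 CPM at 6h, and in dbko at 40 and 52.3 CPM and 53.8 and 61.3 CPM. Against wt at 0h, Rel was lower in cko, at -3.50 ± 0.15 (adjusted p = 4.03e-08) and in dbko, at -3.76 ± 0.15 (adjusted p = 1.93e-08). Relb (ENSMUSG00000002983, chromosome 7, 19606217 to 19629438, minus strand) stood at 115 and 117 CPM in wt at 0h and 149 and 164 CPM at 6h, against 52.9 and 65.6 CPM and 67.8 and 88.3 CPM in dbko, a difference of -0.97 ± 0.14 at 0h (adjusted p = 0.000836) and -1.0 ± 0.14 at 6h (adjusted p = 0.0004). What part of Relb the knockout removes is not given in the sources used here. In cko, which keeps Relb, its level at 0h was 194 and 168 CPM, higher than in wt by 0.64 ± 0.14 (adjusted p = 0.0385), a call that ended with adjusted p = 0.332 without cko 0h replicate 1, 0.142 without cko 0h replicate 2, 0.337 without wt 0h replicate 1, 0.294 without wt 0h replicate 2.

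**Figure D1:**
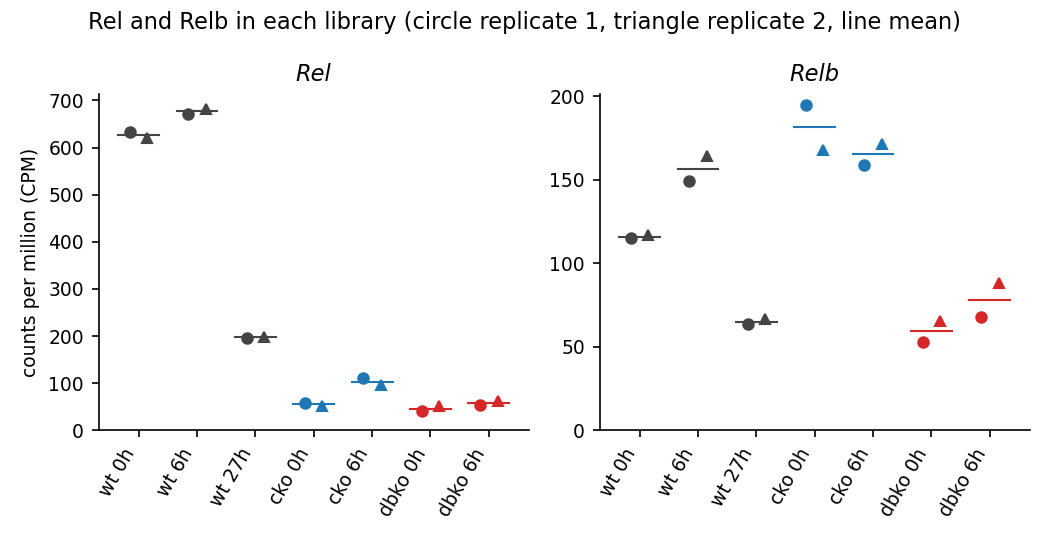
CPM of Rel (left) and Relb (right) in each of the 14 libraries, by genotype and hours with BAFF on the x axis; circles are replicate 1, triangles replicate 2 and lines the mean of both. Rel lies at 620 CPM or above in the wt libraries at 0h and 6h and at 111 CPM or below in every cko and dbko library, and Relb has its lowest mean in dbko at 0h.

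Libraries of one group resembled each other to different degrees. The chi-square statistic per gene between replicates, which is about 1 for pure counting noise, was 2.98 in wt at 27h, 3.23 in wt at 0h, 4.16 in cko at 0h and 5.04 in wt at 6h, against 23.74 in cko at 6h, 33.23 in dbko at 0h and 38.25 in dbko at 6h. None of the pairs agreed within counting noise, and whether the libraries of a group are separate samples is not known. Of the reads tallied, 11.46 and 9.67% lay in no feature in wt at 6h, against 5.57 and 5.69% at 0h and 6.91 and 7.49% at 27h. The shares were 9.76 and 5.21% in cko at 6h against 6.63 and 6.06% at 0h, and 8.48 and 6.22% in dbko at 6h against 6.23 and 6.36% at 0h. The first principal component, with 48.0% of the variance, separated 0h from the later times, and the second, with 22.1%, set dbko replicate 1 apart, at 54.18 at 0h and 53.01 at 6h. Replicate 2 of dbko lay at 16.22 and 12.84 on it, near the wt 27h libraries at 15.81 and 14.97.

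**Figure D2:**
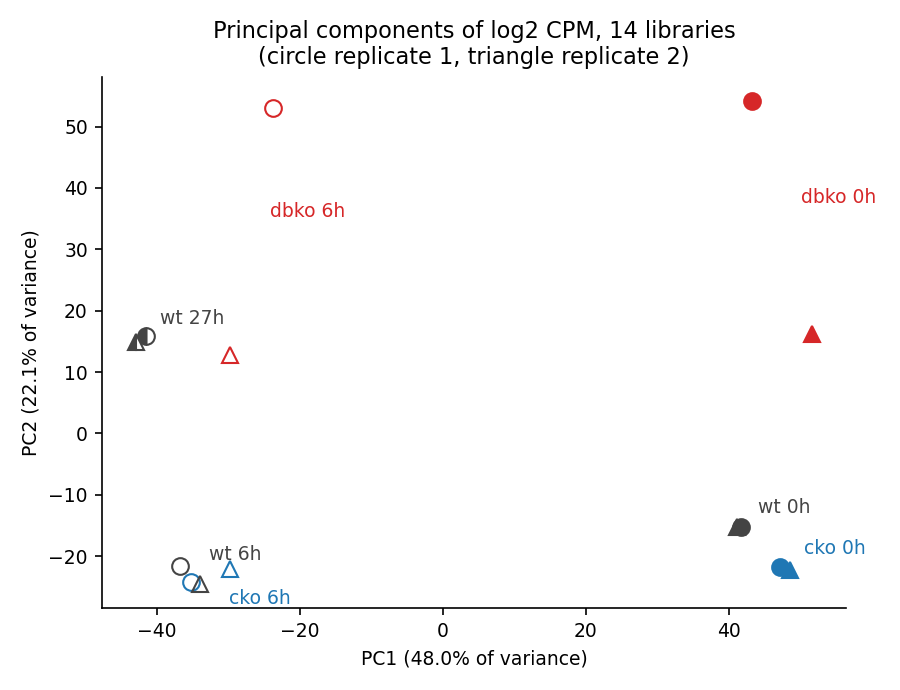
The 14 libraries on principal components 1 and 2 of log2 CPM, each axis with its percent of variance; filled symbols are 0h, open 6h and half-filled 27h, circles replicate 1 and triangles replicate 2, with wt grey, cko blue and dbko red. The 2 dbko libraries of each time lie apart on component 2, 54.18 against 16.22 at 0h, while the wt replicates of 0h lie at -15.3 and -15.27.

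The first comparison asked what 6h with BAFF changed in wt cells. Bcl2l1, which encodes the survival protein Bcl-xL, rose by 2.74 ± 0.18 (adjusted p = 2.93e-07), from 10.5 and 9.67 CPM to 62.7 and 72.3 CPM. Among the largest rises were those of Il2ra, the alpha chain of the interleukin-2 receptor (4.77 ± 0.53), the transcription factor Zbtb46 (4.37 ± 0.29), the chemokines Ccl3 (4.12 ± 0.40) and Ccl4 (3.70 ± 0.40), Ankrd33b (3.52), Igf2r (3.46), the peptide hormone gene Adm (3.31) and the mitophagy receptor Bnip3 (3.30). Most tested genes of ribosome production, glycolysis and cholesterol synthesis rose, and most immediate early, heat shock, interferon-stimulated, migration and antigen presentation genes fell. In total 5830 of 12630 tested genes changed, 2858 higher and 2972 lower, 2458 of them by at least 2-fold.

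Within the MYC and ribosome biogenesis list 33 of 40 rose and 0 fell (as many adjusted over the list alone), with Heatr1 at 1.63, Polr1b at 1.95 and Utp4 at 1.31. Camera on the ribosome biogenesis list gave adjusted p = 7.81e-10, and adjusted p = 0.462 with an estimated correlation. Of the glycolysis genes 16 of 21 rose and 2 fell (as many adjusted over the list alone), led by Pfkp, a phosphofructokinase (2.64), and Aldoa (2.49). Camera on the glycolysis list gave adjusted p = 1.28e-06, and adjusted p = 0.462 with an estimated correlation. Of the cholesterol synthesis genes 20 of 24 rose and 1 fell (as many adjusted over the list alone), among them Lss (2.36), Fdps (1.96) and Sqle (1.81). Camera on the cholesterol synthesis list gave adjusted p = 7.89e-09, and adjusted p = 0.462 with an estimated correlation. Among pro-survival genes 5 of 14 rose and 2 fell (6 and 2 adjusted over the list alone), with Bcl2l2 at 0.90 and Cflar at 0.59 beside Bcl2 at -1.39. Camera on the pro-survival list gave adjusted p = 0.269. Pro-apoptotic genes went both ways: 4 of 17 rose and 4 fell (as many adjusted over the list alone), with the BH3-only genes Pmaip1 at -2.53 and Bcl2l11 at 1.40. Camera on the pro-apoptotic list gave adjusted p = 0.666. Among NF-kB subunits and regulators 6 of 24 rose and 4 fell (as many adjusted over the list alone), with the adaptor Traf1 at 1.29 and Tnfaip3, which encodes the inhibitor A20, at -1.97. Camera on the subunit and regulator list gave adjusted p = 0.573. Known NF-kB targets were divided: 13 of 37 rose and 13 fell (14 and 13 adjusted over the list alone), Slamf1, a lymphocyte surface receptor, at -2.65 and Cd69 at -3.22 among those that fell. Camera on the known target list gave adjusted p = 0.666.

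Among the largest falls were the AP-1 genes Fosb (-8.39 ± 0.40) and Fos (-6.67 ± 0.51), Klf4 (-6.75) and Atf3 (-5.23), and Fosb stood at 3767 and 3831 CPM at 0h. Of the immediate early genes 0 of 23 rose and 20 fell (as many adjusted over the list alone). Camera on the immediate early list gave adjusted p = 5.98e-26, and adjusted p = 0.124 with an estimated correlation. Of the heat shock genes 0 of 13 rose and 13 fell (as many adjusted over the list alone), with Hsph1 at -2.70 and Dnajb1 at -3.08. Camera on the heat shock list gave adjusted p = 1.14e-15, and adjusted p = 0.119 with an estimated correlation. Of the interferon-stimulated genes 0 of 31 rose and 25 fell (0 and 26 adjusted over the list alone), with the regulator Irf7 at -2.66. Camera on the interferon list gave adjusted p = 7.89e-09, and adjusted p = 0.462 with an estimated correlation. Antigen presentation and co-stimulation genes were mostly lower: 2 of 25 rose and 18 fell (as many adjusted over the list alone), H2-DMa at -2.09 and H2-Ab1 at -1.67 against a rise of 2.28 in the co-stimulatory gene Cd86. Camera on the antigen presentation list gave adjusted p = 2.53e-06, and adjusted p = 0.462 with an estimated correlation. Of the migration and adhesion genes 1 of 21 rose and 17 fell (2 and 17 adjusted over the list alone), among them Klf2, a regulator of lymphocyte traffic (-3.27), and the integrin gene Itgb7 (-2.94). Camera on the migration list gave adjusted p = 7.22e-11, and adjusted p = 0.119 with an estimated correlation. Among follicular markers 1 of 19 rose and 12 fell (1 and 13 adjusted over the list alone), Pax5 at -1.19 against Pou2af1 at 1.17. Camera on the follicular marker list gave adjusted p = 9.51e-05, and adjusted p = 0.462 with an estimated correlation. Markers of monocytes and macrophages fell beside these groups: 0 of 16 rose and 12 fell (as many adjusted over the list alone), with Csf1r from 32.5 and 36.8 CPM to 2.19 and 1.19 CPM. Camera on the macrophage list gave adjusted p = 0.000409, and adjusted p = 0.462 with an estimated correlation. Since no culture without BAFF was analysed here, time in culture and BAFF cannot be told apart in any comparison with 0h.

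Extending the culture to 27h in wt cells gave 6012 changed genes against 0h, 2909 higher and 3103 lower. Glycolysis genes were above their 0h levels: 17 of 21 rose and 2 fell (18 and 2 adjusted over the list alone), with a list median of 2.52. For the glycolysis list, camera gave adjusted p = 3.3e-12, and adjusted p = 0.283 with an estimated correlation. Slc16a3, a lactate transporter (7.99 ± 0.91), the prolyl hydroxylase gene Egln3 (7.56 ± 0.83), Aldoc (4.41), Bnip3 (4.26), Tpi1 (4.19), Zbtb32 (4.08) and Eno1 (3.83) were among the largest rises. Bcl2l1 stood 1.91 ± 0.17 above 0h and the survival kinase gene Pim2 2.83 above it, within a pro-survival list of which 4 of 14 rose and 4 fell (as many adjusted over the list alone). For the pro-survival list, camera gave adjusted p = 0.42. Immediate early genes were below 0h: 1 of 23 rose and 22 fell (as many adjusted over the list alone), with Dusp1 at -6.10 and Nr4a2 at -6.61. For the immediate early list, camera gave adjusted p = 3.11e-47, and adjusted p = 0.046 with an estimated correlation. Of the migration and adhesion genes 1 of 21 rose and 16 fell (1 and 17 adjusted over the list alone), with S1pr1, the receptor that guides exit from lymphoid tissue, at -2.70 and Rgs2 at -4.61. For the migration list, camera gave adjusted p = 1.04e-15, and adjusted p = 0.046 with an estimated correlation. Within the NF-kB subunits and regulators 3 of 24 rose and 16 fell (as many adjusted over the list alone), with Rel at -1.67 ± 0.13 and Relb at -0.83 ± 0.14. For the subunit and regulator list, camera gave adjusted p = 0.00347, and adjusted p = 0.689 with an estimated correlation. Of the known targets 7 of 37 rose and 21 fell (as many adjusted over the list alone), with Cd83 at -3.40. For the known target list, camera gave adjusted p = 0.00116, and adjusted p = 0.619 with an estimated correlation. Beside these groups, of the macrophage markers 1 of 16 rose and 8 fell (as many adjusted over the list alone), with a median of -1.99. For the macrophage list, camera gave adjusted p = 0.384. Of the dendritic cell markers 2 of 9 rose and 4 fell (as many adjusted over the list alone), with a median of -2.15. Camera on the dendritic cell list gave adjusted p = 0.511.

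Between 6h and 27h in wt, genes of DNA replication rose and many NF-kB regulators and targets fell. Of the S phase and DNA replication genes 27 of 35 rose and 1 fell (30 and 1 adjusted over the list alone), with the transcription factor gene E2f2 at 1.45, Mcm4 at 1.33 and the replication licensing gene Cdc6 at 2.91. Camera on the S phase list gave adjusted p = 7.91e-10, and adjusted p = 0.686 with an estimated correlation. Of the G2 and mitosis genes 3 of 25 rose and 0 fell (0 and 0 adjusted over the list alone). Camera on the mitosis list gave adjusted p = 0.00288, and adjusted p = 0.828 with an estimated correlation. Of the G1 cyclins and inhibitors 4 of 12 rose and 2 fell (as many adjusted over the list alone), with Ccnd3 at 1.24 and the inhibitor Cdkn1a at 1.65. Camera on the G1 cyclin list gave adjusted p = 0.162. Of the oxidative phosphorylation genes 21 of 40 rose and 0 fell (29 and 0 adjusted over the list alone), with Cox6c at 0.72. Camera on the oxidative phosphorylation list gave adjusted p = 2.71e-07, and adjusted p = 0.686 with an estimated correlation. Within the NF-kB subunits and regulators 0 of 24 rose and 16 fell (0 and 17 adjusted over the list alone), with Rel at -1.78 ± 0.13, Relb at -1.27 ± 0.14 and Nfkbid at -2.31. The subunit and regulator list had a camera adjusted p = 4.63e-07, and adjusted p = 0.657 with an estimated correlation. Among the known targets 5 of 37 rose and 22 fell (as many adjusted over the list alone), with Cd86 at -2.58 and the chemokine receptor Ccr7 at -2.62. The known target list had a camera adjusted p = 4.04e-05, and adjusted p = 0.686 with an estimated correlation. Myc stood at -1.58, Bcl2l1 at -0.83 and Ccl4 at -4.60, while Hmox1, which encodes heme oxygenase 1, rose by 3.05 and the chemokine Ccl22 by 3.20. Of the unfolded protein and amino acid stress genes 12 of 23 rose and 5 fell (as many adjusted over the list alone), with the chaperone genes Hsp90b1 at 1.08 and Manf at 1.26. Camera on the unfolded protein list gave adjusted p = 0.00585, and adjusted p = 0.657 with an estimated correlation. Beside these groups, of the macrophage markers 4 of 16 rose and 0 fell (as many adjusted over the list alone), with a median of 1.12. The macrophage list had a camera adjusted p = 0.00148, and adjusted p = 0.686 with an estimated correlation. In all 4309 genes changed, 2010 higher and 2299 lower. That count was 2100 without wt 27h replicate 1, 2345 without wt 27h replicate 2, 2241 without wt 6h replicate 1 and 2209 without wt 6h replicate 2.

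Over 6h with BAFF, cells lacking c-Rel had 5297 changed genes, 2758 higher and 2539 lower, but 2433 and 2742 with DESeq2 size factors and 2195 and 2610 with DESeq2. Without cko 0h replicates 1 and 2 it was 1791 and 1877, and 1747 and 1810. The chemokine receptor gene Ccr9 (4.26 ± 0.21), Bnip3 (4.09), Adgrl2 (3.59) and Tnfrsf26 (3.46 ± 0.13) were among the largest rises, and Fosb (-8.62 ± 0.41), Hspa1b (-7.67), whose reads can be split with its near copy Hspa1a, and Hsph1 (-5.05 ± 0.18) among the largest falls. Of the glycolysis genes 16 of 21 rose and 1 fell (as many adjusted over the list alone). The glycolysis list had a camera adjusted p = 3.81e-07, and adjusted p = 0.422 with an estimated correlation. Of the cholesterol synthesis genes 16 of 24 rose and 1 fell (as many adjusted over the list alone). For the cholesterol synthesis list, camera gave adjusted p = 1.62e-06, and adjusted p = 0.473 with an estimated correlation. Of the MYC and ribosome biogenesis genes 12 of 40 rose and 2 fell (as many adjusted over the list alone), with Myc itself at -1.92. For the ribosome biogenesis list, camera gave adjusted p = 0.0777. Of the known NF-kB targets 2 of 37 rose and 17 fell (as many adjusted over the list alone). Camera on the known target list gave adjusted p = 6.15e-06, and adjusted p = 0.422 with an estimated correlation. Of the NF-kB subunits and regulators 1 of 24 rose and 7 fell (as many adjusted over the list alone), Nfkbie at -1.07 and Nfkbia at -1.08, both encoding inhibitors of NF-kB. Camera on the subunit and regulator list gave adjusted p = 0.0917. Bcl2l1 stood at 8.14 and 8.25 CPM at 0h and 5.27 and 7.35 CPM at 6h, and of the pro-survival list 3 of 14 rose and 4 fell (as many adjusted over the list alone), with Pim1 at -1.58 and Bcl2 at -1.02. The pro-survival list had a camera adjusted p = 0.584. The cyclin gene Ccnd2 stood at -2.70 in a G1 list of which 3 of 12 rose and 3 fell (as many adjusted over the list alone). For the G1 cyclin list, camera gave adjusted p = 0.612. Of the heat shock genes 0 of 13 rose and 13 fell (as many adjusted over the list alone). For the heat shock list, camera gave adjusted p = 2.87e-41, and adjusted p = 0.0136 with an estimated correlation. Beside these groups, of the erythroid and platelet markers 0 of 11 rose and 6 fell (1 and 6 adjusted over the list alone), with a median of -2.77. Camera on the erythroid list gave adjusted p = 0.0151, and adjusted p = 0.413 with an estimated correlation. Of the immediate early genes 0 of 23 rose and 21 fell (as many adjusted over the list alone). The immediate early list had a camera adjusted p = 1.04e-29, and adjusted p = 0.145 with an estimated correlation.

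The dbko cells changed 5004 genes over the same 6h, 2442 higher and 2562 lower. Ccr9 (4.72 ± 0.20), Mmp19 (4.02), Trib3, a stress-induced pseudokinase gene (3.69 ± 0.22), Dtx4 (3.28) and Hmox1 (3.26 ± 0.23) were among the largest rises, and Fosb (-8.53), Dusp18 (-5.94) and Il1b (-4.91) were among the largest falls. Cholesterol synthesis genes rose here too, as 19 of 24 rose and 1 fell (20 and 1 adjusted over the list alone). The cholesterol synthesis list had a camera adjusted p = 1.59e-08, and adjusted p = 0.501 with an estimated correlation. Of the MYC and ribosome biogenesis genes 4 of 40 rose and 6 fell (3 and 3 adjusted over the list alone). The ribosome biogenesis list had a camera adjusted p = 0.95. Of the glycolysis genes 10 of 21 rose and 3 fell (12 and 3 adjusted over the list alone). Camera on the glycolysis list gave adjusted p = 0.11. Among NF-kB subunits and regulators 3 of 24 rose and 15 fell (4 and 15 adjusted over the list alone), with the survival factors Birc3 at -1.25 ± 0.13 and Birc2 at -0.82. For the subunit and regulator list, camera gave adjusted p = 0.0297, and adjusted p = 0.708 with an estimated correlation. Among their known targets 4 of 37 rose and 20 fell (5 and 22 adjusted over the list alone). For the known target list, camera gave adjusted p = 1.05e-05, and adjusted p = 0.501 with an estimated correlation. Of the pro-survival genes 2 of 14 rose and 5 fell (3 and 5 adjusted over the list alone), with Mcl1 at -0.87. Camera on the pro-survival list gave adjusted p = 0.366. Of the S phase and DNA replication genes 0 of 35 rose and 12 fell (as many adjusted over the list alone). For the S phase list, camera gave adjusted p = 0.00163, and adjusted p = 0.735 with an estimated correlation. Of the immediate early genes 0 of 23 rose and 21 fell (0 and 22 adjusted over the list alone). Camera on the immediate early list gave adjusted p = 1.85e-27, and adjusted p = 0.164 with an estimated correlation. Of the heat shock genes 0 of 13 rose and 12 fell (as many adjusted over the list alone). The heat shock list had a camera adjusted p = 1.34e-18, and adjusted p = 0.147 with an estimated correlation. Erythroid and platelet markers moved with them: 1 of 11 rose and 7 fell (as many adjusted over the list alone), Slc4a1, the red cell anion exchanger, from 330 and 169 CPM to 32.9 and 14.9 CPM. For the erythroid list, camera gave adjusted p = 0.0534. With the replicate number as a block it gave adjusted p = 0.00444. With only the groups compared in the fit, 1323 genes were called, 520 higher and 803 lower, and 49 of 142 genes named by the rule were no longer called, here Birc2.

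**Figure D3:**
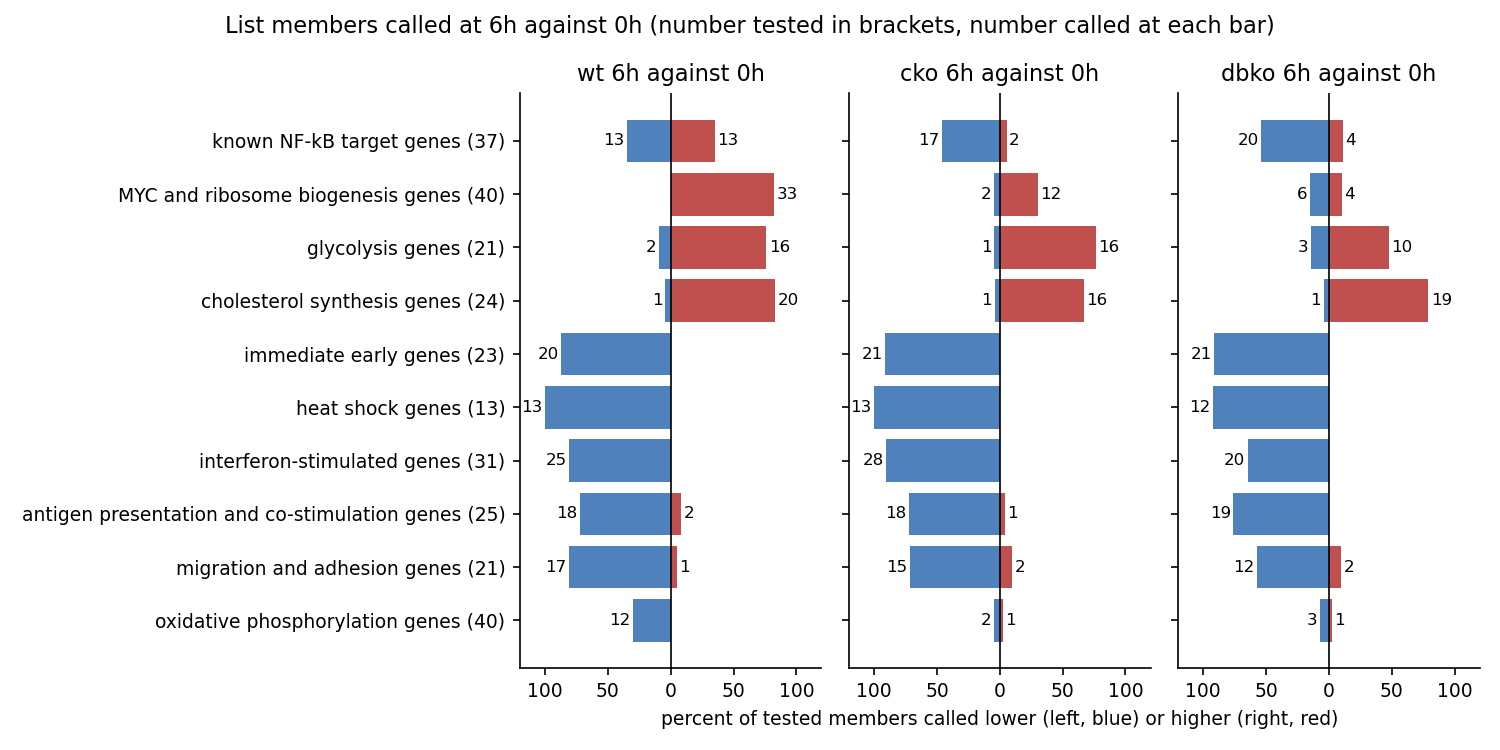
Share of the tested members of 10 gene lists called lower (blue, left) or higher (red, right) at 6h against 0h in wt, cko and dbko, with the number called at each bar and the number tested in brackets. Cholesterol synthesis members rise and immediate early and heat shock members fall in each genotype, while 33 of 40 MYC and ribosome biogenesis genes rise in wt, 12 in cko and 4 in dbko.

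The responses to 6h of culture with BAFF shared many genes across genotypes, in comparisons that have no library in common. Of the 2858 genes that rose in wt, 1874 rose in cko, against 624.1 from independent lists, and 1400 rose in dbko, against 552.6. Of the 2972 that fell in wt, 1961 fell in cko (597.5 from independent lists) and 1619 in dbko (602.9). Opposite calls were fewer, with 28 genes up in wt and down in cko and 105 up in wt and down in dbko. Across genes, which are not independent replicates, the correlation of the fold changes was 0.773 for wt with cko and 0.641 for wt with dbko.

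Whether the 6h response differed between genotypes was tested on the difference itself. Differences are signed, so a gene that fell further counts as lower. Bcl2l1 had a lower 6h fold change in cko than in wt, with a difference of -3.11 ± 0.26 (adjusted p = 0.000331), and in dbko than in wt, with a difference of -2.15 ± 0.25 (adjusted p = 0.000462). In cko 215 genes responded differently from wt, 70 with a higher and 145 with a lower 6h fold change. DESeq2 size factors gave 50 and 177. Fitting only the groups compared gave 1290, 578 higher and 712 lower. Among the 215, Hmox1 (2.75 ± 0.32, adjusted p = 0.00283) was higher, and heat shock genes Hsph1 (-2.35 ± 0.22) and Dnaja1 (-1.18) lower. Each lay the other way at 0h, which adds to these values. Within the known NF-kB targets 0 of 37 had a higher 6h fold change and 6 a lower one (0 and 15 adjusted over the list alone). The known target list had a camera adjusted p = 8.71e-14, and adjusted p = 0.245 with an estimated correlation. Of the NF-kB subunits and regulators 0 of 24 had a higher 6h fold change and 3 a lower one (2 and 8 adjusted over the list alone). The subunit and regulator list had a camera adjusted p = 7.52e-06, and adjusted p = 0.591 with an estimated correlation. Of the heat shock genes 0 of 13 had a higher 6h fold change and 6 a lower one (0 and 13 adjusted over the list alone). Camera on the heat shock list gave adjusted p = 6.17e-23, and adjusted p = 0.091 with an estimated correlation. Among MYC and ribosome biogenesis genes 0 of 40 had a higher 6h fold change and 1 a lower one (0 and 11 adjusted over the list alone). Camera on the ribosome biogenesis list gave adjusted p = 9.18e-15, and adjusted p = 0.591 with an estimated correlation. Beside these groups, of the macrophage markers 1 of 16 had a higher 6h fold change and 0 a lower one (2 and 0 adjusted over the list alone), with a median difference of 1.72. Camera on the macrophage list gave adjusted p = 2.37e-05, and adjusted p = 0.591 with an estimated correlation. The count of 215 was 17 without cko 0h replicate 1, 18 without cko 0h replicate 2, 409 without cko 6h replicate 1, 35 without cko 6h replicate 2, 9 without wt 0h replicate 1, 16 without wt 0h replicate 2, 34 without wt 6h replicate 1 and 17 without wt 6h replicate 2.

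In dbko 1749 genes responded differently from wt, 872 with a higher and 877 with a lower 6h fold change. Zbtb46 (-4.75 ± 0.39), Ccl4 (-3.33 ± 0.54), Il1r2 (-3.09), Ccl3 (-3.00) and Ctse (-2.88) were among the lowest relative to wt, and Osgin1 (3.15 ± 0.41) and Hmox1 (3.12 ± 0.31) were higher. Of the NF-kB subunits and regulators 1 of 24 had a higher 6h fold change and 7 a lower one (1 and 8 adjusted over the list alone), with Traf1 at -1.82 ± 0.19, Birc2 at -1.09, Birc3 at -1.05 and Nfkbiz at -1.86. Camera on the subunit and regulator list gave adjusted p = 0.000119, and adjusted p = 0.538 with an estimated correlation. Of their known targets 0 of 37 had a higher 6h fold change and 10 a lower one (0 and 11 adjusted over the list alone), with Tnf at -2.28 and Cd86 at -1.78. Camera on the known target list gave adjusted p = 8.73e-07, and adjusted p = 0.48 with an estimated correlation. Of the MYC and ribosome biogenesis genes 0 of 40 had a higher 6h fold change and 22 a lower one (0 and 28 adjusted over the list alone), with Gnl3 at -1.56 ± 0.22, Rrp12 at -1.71 and Nolc1 at -1.49. For the ribosome biogenesis list, camera gave adjusted p = 1.83e-16, and adjusted p = 0.48 with an estimated correlation. Of the glycolysis genes 0 of 21 had a higher 6h fold change and 6 a lower one (1 and 8 adjusted over the list alone), with Slc16a1 at -1.32. For the glycolysis list, camera gave adjusted p = 1.38e-05, and adjusted p = 0.538 with an estimated correlation. Of the marginal zone B cell markers 7 of 16 had a higher 6h fold change and 0 a lower one (as many adjusted over the list alone), with Cd36 at 2.23 and S1pr3 at 2.05. Camera on the marginal zone list gave adjusted p = 7.08e-07, and adjusted p = 0.458 with an estimated correlation. Tnfrsf13b, which encodes the BAFF and APRIL receptor TACI, was higher, at 1.42 ± 0.19 (adjusted p = 0.000881). Macrophage markers moved with these groups: 9 of 16 had a higher 6h fold change and 0 a lower one (14 and 0 adjusted over the list alone). For the macrophage list, camera gave adjusted p = 6.95e-08, and adjusted p = 0.48 with an estimated correlation. The count was 2638 without dbko 6h replicate 2, 595 and 614 without wt 0h replicates 1 and 2, and 741 and 596 without wt 6h replicates 1 and 2. A fit of only the groups compared gave 651, and 43 of 92 genes named by the rule were no longer called.

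The 6h responses of the 2 knockouts differed from each other for 118 genes, 74 higher and 44 lower in dbko, but for 1 gene with only the groups compared in the fit. In that fit 32 of the 33 genes named by the rule were no longer called. S1pr3 (2.02 ± 0.23), Tent5c (1.91 ± 0.17) and Hsph1 (1.90 ± 0.22) had a higher 6h fold change in dbko. Ctse (-2.60 ± 0.31) and Abcb4 (-2.33) had a lower one. Tent5c and Hsph1 fell less far, Hsph1 from lower 0h levels. Of the heat shock genes 6 of 13 had a higher 6h fold change and 0 a lower one (12 and 0 adjusted over the list alone). For the heat shock list, camera gave adjusted p = 1.76e-27, and adjusted p = 0.0547 with an estimated correlation. The 118 became 17 and 12 without cko 0h replicates 1 and 2, 19 and 60 without cko 6h replicates 1 and 2, 64 and 619 without dbko 0h replicates 1 and 2, and 682 without dbko 6h replicate 2.

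**Figure D4:**
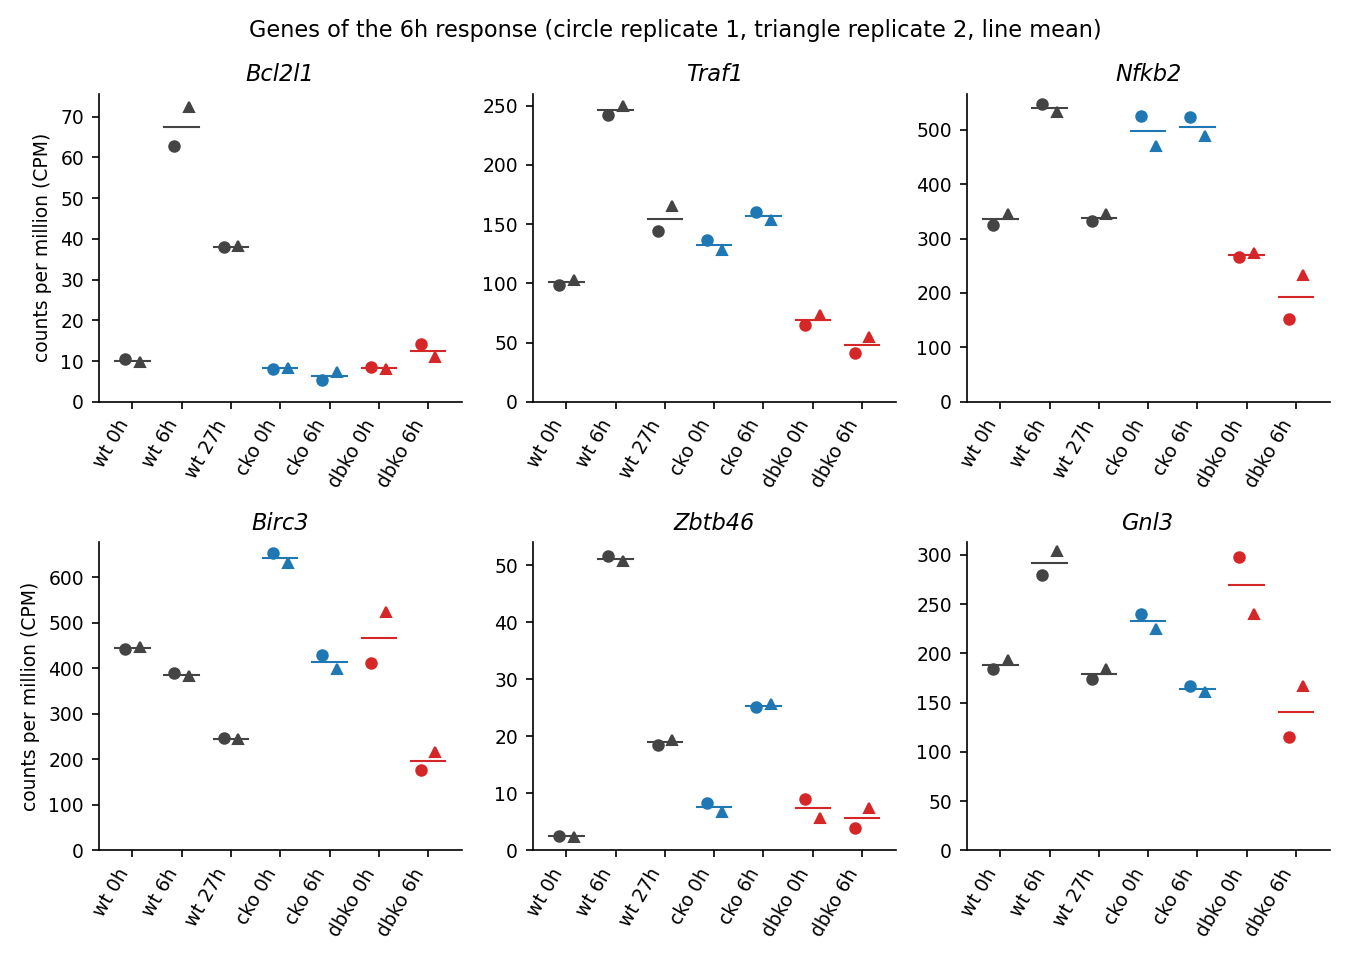
CPM of 6 genes in each of the 14 libraries, by genotype and hours with BAFF on the x axis; circles are replicate 1, triangles replicate 2 and lines the mean of both. Bcl2l1 reaches 62.7 and 72.3 CPM in wt at 6h and stays at 14.2 CPM or below in every cko and dbko library, and Traf1 is lowest in dbko at 6h.

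Before culture, cko and wt cells differed in 189 genes, 116 higher and 73 lower in cko. With only these groups in the fit the count was 2661, 1426 higher and 1235 lower, so its size depends on the fit. Heat shock genes were higher in cko: of the list 9 of 13 were higher and 0 lower (12 and 0 adjusted over the list alone), with Hsph1 at 1.56 ± 0.16 (adjusted p = 0.000223), Dnaja1 at 0.81 and Hspd1 at 0.98. The heat shock list had a camera adjusted p = 1.09e-31, and adjusted p = 0.0361 with an estimated correlation. Also higher were Tagap1 (1.48 ± 0.14) and Pea15a (1.44 ± 0.12), and lower were Sfn, which encodes 14-3-3 sigma (-2.77 ± 0.24), Hmox1 (-2.27 ± 0.24) and the interferon-inducible family members Ifi213 (-4.26 ± 0.31) and Ifi206 (-1.96), whose near copies can share reads. Markers of other cells differed beside these groups. Of the monocyte and macrophage markers 0 of 16 were higher and 5 lower (0 and 11 adjusted over the list alone), with Adgre1, which encodes F4/80, at -1.17 and Csf1r at 2.01 and 2.48 CPM against 32.5 and 36.8 CPM. The macrophage list had a camera adjusted p = 9.8e-17, and adjusted p = 0.122 with an estimated correlation. Of the erythroid and platelet markers 2 of 11 were higher and 0 lower (5 and 0 adjusted over the list alone). The erythroid list had a camera adjusted p = 5.9e-06, and adjusted p = 0.105 with an estimated correlation. The count of 189 was 48 without cko 0h replicate 1, 41 without cko 0h replicate 2, 38 (16 higher, 22 lower) without wt 0h replicate 1 and 46 (21 and 25) without wt 0h replicate 2.

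The dbko cells differed from wt at 0h in 1472 genes, 897 higher and 575 lower. Among NF-kB subunits and regulators 0 of 24 were higher and 6 lower (as many adjusted over the list alone). For the subunit and regulator list, camera gave adjusted p = 1.93e-05, and adjusted p = 0.376 with an estimated correlation. Of the known targets 1 of 37 were higher and 13 lower (2 and 14 adjusted over the list alone), with Slamf1 at -0.81 and Bcl2a1b, an anti-apoptotic gene with near copies, at -1.75. For the known target list, camera gave adjusted p = 1.82e-05, and adjusted p = 0.351 with an estimated correlation. Il9r (-4.92 ± 0.55), the apolipoprotein gene Apoe (-3.78 ± 0.20), whose locus adjoins Relb, and Sfn (-3.34 ± 0.25) were among the largest differences below wt. Of the migration and adhesion genes 1 of 21 were higher and 7 lower (as many adjusted over the list alone), with Klf2 at -1.28 and S1pr2 at -1.44. The migration list had a camera adjusted p = 0.000649, and adjusted p = 0.332 with an estimated correlation. Of the pro-survival genes 1 of 14 were higher and 5 lower (2 and 5 adjusted over the list alone), with Cflar at -0.69. For the pro-survival list, camera gave adjusted p = 0.0433, and adjusted p = 0.332 with an estimated correlation. Of the immediate early genes 0 of 23 were higher and 8 lower (1 and 13 adjusted over the list alone), with Jun at -1.57. For the immediate early list, camera gave adjusted p = 2.8e-07, and adjusted p = 0.351 with an estimated correlation. Of the antigen presentation genes 1 of 25 were higher and 5 lower (2 and 14 adjusted over the list alone), with H2-Oa at -0.98. For the antigen presentation list, camera gave adjusted p = 1.82e-05, and adjusted p = 0.332 with an estimated correlation.

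Erythroid and dendritic cell markers were higher in dbko beside these groups. Slc4a1 was higher by 6.58 ± 0.50 (adjusted p = 4.02e-05), at 330 and 169 CPM against 1.98 and 3.19 CPM, followed by the spectrin gene Sptb (6.49), Car1 (6.45), Aqp1 (6.15) and Ank1 (5.72). Of the erythroid and platelet markers 8 of 11 were higher and 0 lower (as many adjusted over the list alone). Camera on the erythroid list gave adjusted p = 6.52e-20, and adjusted p = 0.011 with an estimated correlation. Of the S phase and DNA replication genes 17 of 35 were higher and 0 lower (26 and 0 adjusted over the list alone). The S phase list had a camera adjusted p = 1.34e-10, and adjusted p = 0.384 with an estimated correlation. Of the G2 and mitosis genes 3 of 25 were higher and 0 lower (21 and 0 adjusted over the list alone). For the mitosis list, camera gave adjusted p = 1.11e-06, and adjusted p = 0.512 with an estimated correlation. Of the dendritic cell markers 6 of 9 were higher and 0 lower (as many adjusted over the list alone), with Itgax at 1.86. For the dendritic cell list, camera gave adjusted p = 2.8e-06, and adjusted p = 0.076 with an estimated correlation. Of the monocyte and macrophage markers 2 of 16 were higher and 0 lower (2 and 1 adjusted over the list alone). Camera on the macrophage list gave adjusted p = 0.355. Of the follicular markers 0 of 19 were higher and 3 lower (as many adjusted over the list alone). For the follicular marker list, camera gave adjusted p = 0.000632, and adjusted p = 0.351 with an estimated correlation. The count of 1472 was 600 and 3089 without dbko 0h replicates 1 and 2, 462 and 445 without wt 0h replicates 1 and 2, and 4717 with both second-replicate dbko libraries left out, a choice made after seeing the data. With only the groups compared in the fit it was 416, and 47 of 93 genes named by the rule were no longer called, here Cflar and H2-Oa.

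**Figure D5:**
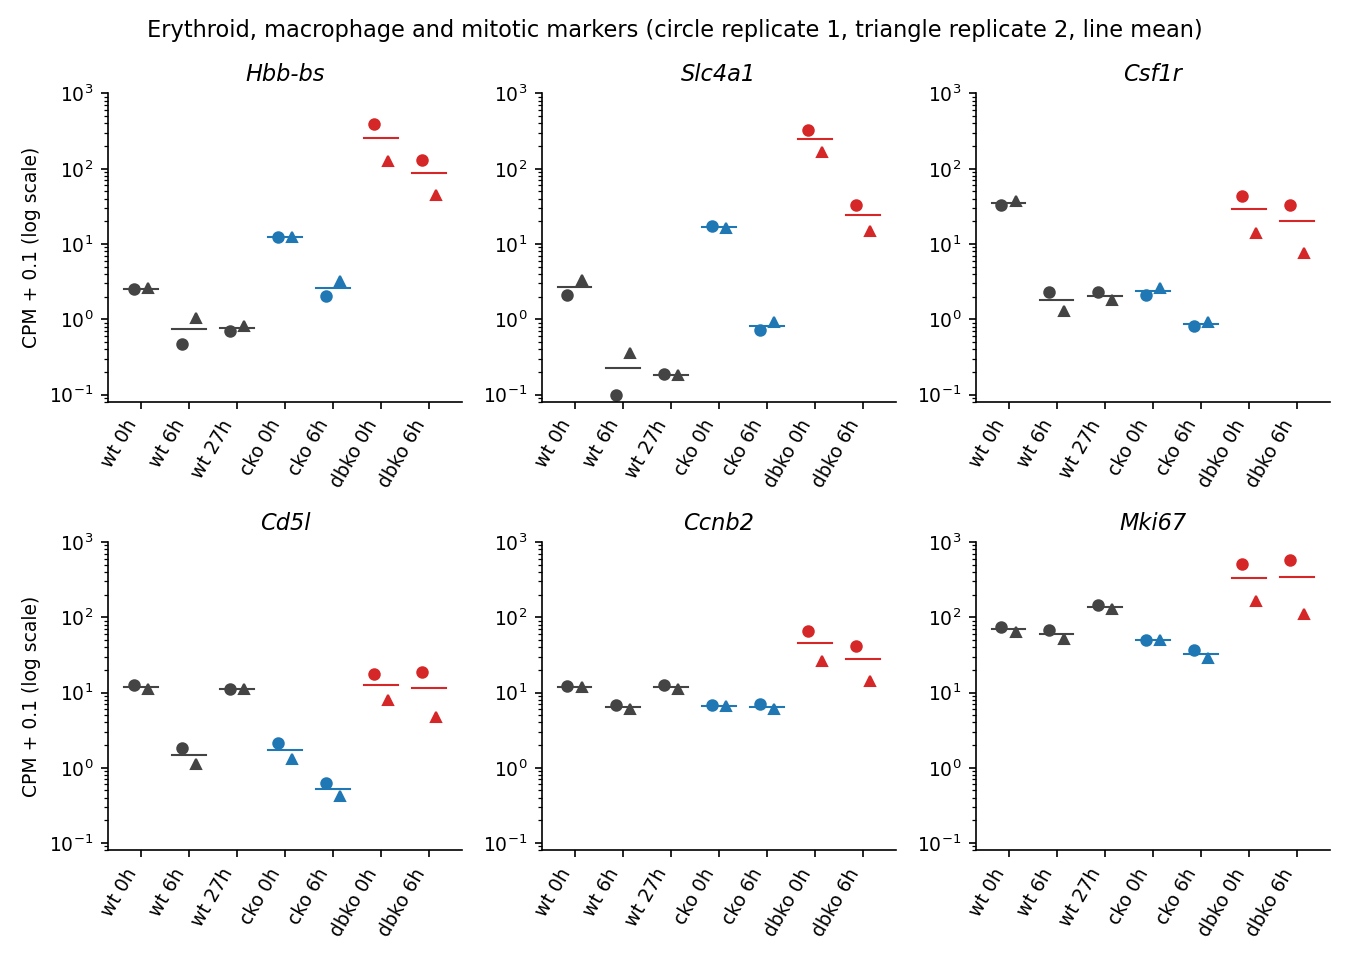
CPM plus 0.1, on a log axis, of 2 erythroid genes (Hbb-bs, whose near copy can share its reads, and Slc4a1), 2 macrophage genes (Csf1r, Cd5l) and 2 mitotic genes (Ccnb2, Mki67) in each of the 14 libraries, by genotype and hours with BAFF; circles are replicate 1, triangles replicate 2 and lines the mean of both. In dbko replicate 1 lies above replicate 2 for each of the 6 genes, for Mki67 at 503 against 166 CPM at 0h.

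Against cko at 0h, dbko differed in 1140 genes, 838 higher and 302 lower. Relb was lower, at -1.61 ± 0.14 (adjusted p = 5.82e-05), and of the NF-kB subunits and regulators 0 of 24 were higher and 7 lower (0 and 9 adjusted over the list alone), with Traf1 at -0.94 ± 0.13. The subunit and regulator list had a camera adjusted p = 2.33e-08, and adjusted p = 0.308 with an estimated correlation. Il9r (-6.09 ± 0.55), Apoe (-3.48 ± 0.19), Rasgrp3, an activator of Ras (-2.33), Pglyrp1 (-2.15), Slc1a5 (-2.06) and Chst10 (-2.04 ± 0.12) were lower. Of the heat shock genes 0 of 13 were higher and 12 lower (0 and 13 adjusted over the list alone), with Hsph1 at -1.65. Camera on the heat shock list gave adjusted p = 3.56e-24, and adjusted p = 0.0416 with an estimated correlation. Of the known NF-kB targets 3 of 37 were higher and 12 lower (3 and 15 adjusted over the list alone). The known target list had a camera adjusted p = 2.33e-08, and adjusted p = 0.308 with an estimated correlation. Markers of other and of dividing cells were higher: of the erythroid and platelet list 8 of 11 were higher and 0 lower (10 and 0 adjusted over the list alone). For the erythroid list, camera gave adjusted p = 5.69e-16, and adjusted p = 0.0269 with an estimated correlation. Of the macrophage list 12 of 16 were higher and 0 lower (13 and 0 adjusted over the list alone). For the macrophage list, camera gave adjusted p = 4.31e-14, and adjusted p = 0.19 with an estimated correlation. Of the S phase list 22 of 35 were higher and 0 lower (32 and 0 adjusted over the list alone). Camera on the S phase list gave adjusted p = 3.56e-17, and adjusted p = 0.308 with an estimated correlation. Of the G2 and mitosis list 13 of 25 were higher and 0 lower (25 and 0 adjusted over the list alone). The mitosis list had a camera adjusted p = 1.26e-15, and adjusted p = 0.308 with an estimated correlation. The count was 254 and 227 without cko 0h replicates 1 and 2, 362 and 3014 without dbko 0h replicates 1 and 2, and 4528 with both second-replicate dbko libraries left out. A fit of only the groups compared gave 545, and 43 of 102 genes named by the rule were no longer called.

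After 6h with BAFF, cko differed from wt in 447 genes, 199 higher and 248 lower. Bcl2l1 was lower at -3.41 ± 0.18 (adjusted p = 4.28e-07), as were Rel (-2.71 ± 0.14), Plau, the urokinase gene (-2.37 ± 0.29), Cdk5r1 (-2.36 ± 0.30), Sfn (-2.31 ± 0.22) and Pus10 (-2.14 ± 0.21), the last of which lies beside Rel. Il2ra was lower too (-2.66 ± 0.45), with adjusted p = 0.0631 without cko 6h replicate 1, 0.121 without cko 6h replicate 2, 0.0796 without wt 6h replicate 1, 0.0978 without wt 6h replicate 2. Of the known NF-kB targets 0 of 37 were higher and 14 lower (0 and 19 adjusted over the list alone), with the adhesion gene Icam1 at -1.21 ± 0.15 and Bcl2a1b at -1.66 ± 0.23. Camera on the known target list gave adjusted p = 2.1e-17, and adjusted p = 0.135 with an estimated correlation. Of the pro-survival genes 0 of 14 were higher and 4 lower (as many adjusted over the list alone). The pro-survival list had a camera adjusted p = 4.8e-07, and adjusted p = 0.0592 with an estimated correlation. Of the NF-kB subunits and regulators 0 of 24 were higher and 6 lower (0 and 7 adjusted over the list alone). Camera on the subunit and regulator list gave adjusted p = 3.08e-07, and adjusted p = 0.384 with an estimated correlation. Of the MYC and ribosome biogenesis genes 0 of 40 were higher and 5 lower (0 and 18 adjusted over the list alone). The ribosome biogenesis list had a camera adjusted p = 2.47e-15, and adjusted p = 0.384 with an estimated correlation. Cdk6 (-0.97), Slamf7 (-1.18) and Plscr1 (-1.27) were lower, and Zfp69 (1.46) and Plac8 (1.20 ± 0.15) higher. Relb did not pass the test, at 0.08 ± 0.14 (adjusted p = 0.837). The count of 447 was 103 without cko 6h replicate 2, 98 without wt 6h replicate 1 and 70 without wt 6h replicate 2.

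At 6h dbko differed from wt in 3370 genes, 1920 higher and 1450 lower. Of the known NF-kB targets 0 of 37 were higher and 24 lower (0 and 25 adjusted over the list alone), with Traf1 at -2.37 ± 0.14, Bcl2l1 at -2.42 ± 0.17, Icam1 at -1.24 and Nfkb2, which encodes p100, at -1.49 ± 0.16. For the known target list, camera gave adjusted p = 7.17e-20, and adjusted p = 0.103 with an estimated correlation. Of the NF-kB subunits and regulators 0 of 24 were higher and 13 lower (0 and 14 adjusted over the list alone). For the subunit and regulator list, camera gave adjusted p = 9.15e-16, and adjusted p = 0.135 with an estimated correlation. Of the pro-survival genes 1 of 14 were higher and 8 lower (as many adjusted over the list alone), with Birc3 at -0.98, Bcl2a1b at -1.96 and Cflar at -0.94. Camera on the pro-survival list gave adjusted p = 2.56e-07, and adjusted p = 0.0569 with an estimated correlation. Among the largest differences below wt were Il9r (-5.29 ± 0.48), Cdk5r1 (-3.77 ± 0.33), Grasp (-3.62), Rel, Ccl4 (-3.43), Apoe (-3.41) and Zbtb46 (-3.17 ± 0.25). Of the MYC and ribosome biogenesis list 0 of 40 were higher and 19 lower (0 and 23 adjusted over the list alone), with Gnl3 at -1.05 and Polr1b at -1.19. Camera on the ribosome biogenesis list gave adjusted p = 4.81e-11, and adjusted p = 0.371 with an estimated correlation. Of the glycolysis list 0 of 21 were higher and 8 lower (as many adjusted over the list alone), with the glucose transporter Slc2a3 at -1.67. The glycolysis list had a camera adjusted p = 5.87e-06, and adjusted p = 0.371 with an estimated correlation. Of the antigen presentation and co-stimulation genes 0 of 25 were higher and 8 lower (0 and 9 adjusted over the list alone), with Cd83 at -1.51 and Cd86 at -1.16. The antigen presentation list had a camera adjusted p = 3.27e-05, and adjusted p = 0.303 with an estimated correlation. Of the marginal zone markers 6 of 16 were higher and 0 lower (as many adjusted over the list alone), with Cd9 at 1.45. For the marginal zone list, camera gave adjusted p = 0.000424, and adjusted p = 0.283 with an estimated correlation. Fcer2a, which encodes CD23 of follicular cells, stood at -1.67 ± 0.17 in a follicular list of which 3 of 19 were higher and 6 lower (4 and 6 adjusted over the list alone). The follicular marker list had a camera adjusted p = 0.0292, and adjusted p = 0.527 with an estimated correlation. Tnfrsf13b was higher by 1.03 ± 0.13 (adjusted p = 0.00024).

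Markers of other cells differed beside these groups at 6h. Each tested monocyte and macrophage marker was higher, as 16 of 16 were higher and 0 lower (as many adjusted over the list alone), with Lyz2 at 47.6 and 12.9 CPM against 1.74 and 0.509 CPM. The macrophage list had a camera adjusted p = 6.94e-11, and adjusted p = 0.268 with an estimated correlation. Of the erythroid and platelet markers 10 of 11 were higher and 0 lower (as many adjusted over the list alone). The erythroid list had a camera adjusted p = 1.42e-12, and adjusted p = 0.0569 with an estimated correlation. Of the G2 and mitosis genes 25 of 25 were higher and 0 lower (as many adjusted over the list alone), with Ccnb2 at 42 and 14.1 CPM against 6.68 and 6.03 CPM. Camera on the mitosis list gave adjusted p = 5.03e-08, and adjusted p = 0.432 with an estimated correlation. Of the S phase genes 14 of 35 were higher and 0 lower (25 and 1 adjusted over the list alone). For the S phase list, camera gave adjusted p = 3.27e-05, and adjusted p = 0.595 with an estimated correlation. The 3370 genes became 2170 without dbko 6h replicate 1, 1494 and 1296 without wt 6h replicates 1 and 2, and 5647 with both second-replicate dbko libraries left out. With only the groups compared in the fit 509 were higher and 566 lower, and 56 of 136 genes named by the rule were no longer called, here Cd86 and Cd9.

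Between the 2 knockouts at 6h, 1696 genes differed, 1108 higher and 588 lower in dbko. Traf1 (-1.72 ± 0.13), Nfkb2 (-1.39 ± 0.16), Birc3 (-1.08 ± 0.13) and Relb (-1.08 ± 0.14) led the NF-kB subunits and regulators, of which 0 of 24 were higher and 7 lower (0 and 8 adjusted over the list alone). The subunit and regulator list had a camera adjusted p = 1.51e-09, and adjusted p = 0.303 with an estimated correlation. Of the known NF-kB targets 3 of 37 were higher and 7 lower (4 and 11 adjusted over the list alone), with Cd86 at -1.60 ± 0.24. The known target list had a camera adjusted p = 6.05e-06, and adjusted p = 0.303 with an estimated correlation. Il9r (-6.10 ± 0.49), Apoe (-4.29 ± 0.19), Rhbdf1 (-3.51), Gad1 (-3.20), Itgb3 (-3.08), Chst10 (-2.69 ± 0.12) and P2ry10 (-2.62) were lower, as were Pou2af1, a co-activator of B cell genes (-1.77) and Zbtb46 (-2.16). Of the B-1 cell markers 8 of 9 were higher and 0 lower (9 and 0 adjusted over the list alone), with Tbc1d9 at 2.20, Zbtb32 at 2.59 and Plscr1 at 1.10. Camera on the B-1 marker list gave adjusted p = 1.2e-10, and adjusted p = 0.0258 with an estimated correlation. Cd36 (1.55), Tnfrsf13b (1.00) and Tnfrsf13c, the gene of the BAFF receptor (0.66), were higher. Macrophage, erythroid and mitotic transcripts differed beside them: of the macrophage markers 16 of 16 were higher and 0 lower (as many adjusted over the list alone). Camera on the macrophage list gave adjusted p = 4.88e-19, and adjusted p = 0.188 with an estimated correlation. Of the erythroid and platelet markers 9 of 11 were higher and 0 lower (10 and 0 adjusted over the list alone). Camera on the erythroid list gave adjusted p = 1.99e-16, and adjusted p = 0.0258 with an estimated correlation. Of the G2 and mitosis genes 25 of 25 were higher and 0 lower (as many adjusted over the list alone). For the mitosis list, camera gave adjusted p = 1.99e-16, and adjusted p = 0.303 with an estimated correlation. The count was 559 and 870 without cko 6h replicates 1 and 2, 733 and 3019 without dbko 6h replicates 1 and 2, and 4464 with both second-replicate dbko libraries left out. A fit of only the groups compared gave 190, and 78 of 112 genes named by the rule were no longer called, here Cd86, Itgb3, Plscr1, Tnfrsf13b and Tnfrsf13c.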

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

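All tests of explanations in this part were chosen after the result was seen, except the one on shares of macrophages or erythroid cells between dbko replicates. The 6h response differed between genotypes by a test of the difference itself, for 215 genes in cko against wt, 1749 in dbko against wt and 118 in dbko against cko. Values are signed differences of 6h log2 fold changes among genes chosen by the preset rule, so a lower one can be a smaller rise or larger fall. Macrophage markers had medians of 1.72 and 3.04 in cko and dbko against wt, so other cells may add to higher values.

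In cko against wt, Hmox1 (2.75), Osgin1 (1.92), Hes1 (1.51), Pagr1a (1.39), Gfod1 (1.31), S1pr4 (1.29), Jun (1.22) and Plac8 (1.20) were higher. Bcl2l1 (-3.11), Zbtb46 (-2.63), Mir155hg (-2.48), Cdk5r1 (-2.43), Hsph1 (-2.35), Vsir (-2.25), Jcad (-2.16), Arl5b (-2.06), Nfkbiz (-1.69), Icam1 (-1.21), Nfkbie (-1.15), Gnl3 (-1.14) and Traf1 (-1.05) were lower. Of these 21 genes, the number no longer called was 16 without cko 0h replicate 1 (adjusted p 0.0596 to 0.182), 15 without cko 0h replicate 2 (0.0669 to 0.216), 2 without cko 6h replicate 1 (0.054 to 0.0572), 15 without cko 6h replicate 2 (0.0511 to 0.182), 18 without wt 0h replicate 1 (0.0531 to 0.181), 17 without wt 0h replicate 2 (0.0575 to 0.22), 13 without wt 6h replicate 1 (0.0563 to 0.15) and 16 without wt 6h replicate 2 (0.0621 to 0.219). The calls of Hmox1, Bcl2l1 and Hsph1 held in each of these.

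In dbko against wt, Csf1r (3.85), Vcam1 (3.42), Lrp1 (3.40), Osgin1 (3.15), Hmox1 (3.12), Ighg2b (3.05), Slc40a1 (3.04) and Cdh17 (2.72) were higher. Zbtb46 (-4.75), Il2ra (-3.67), Ccl4 (-3.33), Il1r2 (-3.09), Ccl3 (-3.00), Car2 (-2.93), Ctse (-2.88), Grasp (-2.72), Tnf (-2.28), Bcl2l1 (-2.15), Nfkbiz (-1.86), Traf1 (-1.82), Rrp12 (-1.71), Gnl3 (-1.56), Nolc1 (-1.49), Utp4 (-1.28), Birc2 (-1.09) and Birc3 (-1.05) were lower. Of these 26 genes, the number no longer called was 4 without dbko 0h replicate 2 (adjusted p 0.0545 to 0.0766), 3 without dbko 6h replicate 1 (0.0511 to 0.0862), 7 without wt 0h replicate 1 (0.0571 to 0.167), 7 without wt 0h replicate 2 (0.0512 to 0.109), 5 without wt 6h replicate 1 (0.083 to 0.148), 8 without wt 6h replicate 2 (0.0533 to 0.173) and 7 with only the groups compared (0.051 to 0.104).

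In dbko against cko, Myof (2.49), Pde4a (2.29), Cxcl16 (2.21), Emid1 (2.14), S1pr3 (2.02), Plin2 (1.96), Tent5c (1.91) and Hsph1 (1.90) were higher. Ctse (-2.60), Abcb4 (-2.33), Zbtb46 (-2.13), Mxi1 (-2.03), Cd86 (-1.99), Ptdss2 (-1.92), Cpox (-1.90), Steap3 (-1.86) and Tnf (-1.40) were lower. Of these 17 genes, the number no longer called was 12 without cko 0h replicate 1 (adjusted p 0.0659 to 0.205), 12 without cko 0h replicate 2 (0.0695 to 0.225), 12 without cko 6h replicate 1 (0.0542 to 0.184), 11 without cko 6h replicate 2 (0.0512 to 0.134), 6 without dbko 0h replicate 1 (0.0575 to 0.114), 1 without dbko 6h replicate 1 (0.0653) and 16 with only the groups compared (0.0856 to 0.307).

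Erythroid, macrophage and mitotic transcripts, Csf1r among them, were higher in dbko than in wt libraries in at least 1 of the 2 times, although the bead isolation of follicular B cells is meant to remove other cells; of the 12 erythroid and platelet markers 4 reached 1 CPM in both wt libraries at 0h and 0 are in another list. An equal rise of other cells is argued against by erythroid and T cell median fold changes of 5.94 and -0.273, 6.21 apart at 0h. Quartiles were 2.79 to 6.64 and -0.405 to 0.796. A lower B cell share from erythroid RNA stays open. Macrophage RNA may carry the mitotic transcripts: at 0h the G2 and mitosis median lay 1.33 above the macrophage one (1.58 against 0.248), but 15 of 16 macrophage markers reached 1 CPM in both wt libraries, which can hide an added share, and at 6h the macrophage median was the higher (3.04 against 2.22). Erythroid RNA may carry them: from 0h to 6h in dbko the erythroid median lay 1.81 below the mitotic one (-1.80 against 0.0106), but the quartiles of members, -2.13 to -0.159 and -0.421 to 0.262, overlap. An untested effect of the genotype on cells of the spleen stays open.

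Libraries of dbko at one time differed more from each other than those of wt, with replicate 1 above replicate 2 by a median of 1.35 for G2 and mitosis genes at 0h and 1.74 at 6h, and of 0.927 and 1.48 for macrophage markers. Depth is argued against by a smaller library at 94.1% of the larger one, and the sequencing lane by a gap in G2 and mitosis genes of 0.0496 at most in wt and cko at 0h and 6h and, for all genes at 0h, by a correlation of deviations with wt and cko of 0.017 at most. For all genes at 6h a part of the lane stays open, since these correlations were 0.195 and 0.178 while other pairs of groups reached -0.268. Different shares of macrophages or erythroid cells may contribute: over the 897 genes higher in dbko than in wt at 0h replicate 1 lay above replicate 2 by a median of 0.444, between the bounds set beforehand and short of 0.5, and the median over follicular markers was -0.364. No further biological explanation was tested, since the labels say nothing on how the replicates differ.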

How the results depend on the processing

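Only the block within genotypes and leaving out first or second dbko replicates were chosen after seeing the data. Numbers of called genes stayed within 1.5 times those reported with DESeq2 size factors and with the replicate block in all 14 comparisons, and no named gene reversed its direction in any alternative. With DESeq2 size factors the median fold change of all genes moved most in cko at 6h against 0h, by -0.0507. The majority of higher or lower genes turned there, from 2758 higher and 2539 lower to 2433 and 2742, as it did with DESeq2 (2195 and 2610), with no filter (2490 and 2933) and without cko 0h replicate 1 or 2. It also turned for cko against wt at 0h without wt 0h replicate 1 or 2 (16 and 22, 21 and 25). With only the groups compared it turned for wt at 27h against 0h (4258 and 4196) and dbko against wt at 6h (509 and 566). The near even balance of the response of dbko against wt (872 and 877) turned in 5 alternatives, and that of dbko against cko (74 and 44) without the second dbko replicates (1016 and 1064).

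With only the groups compared in the fit, which changes the residual degrees of freedom, the number of called genes was 7507 for wt at 27h against 6h, 1323 for dbko at 6h against 0h, 2661 for cko against wt at 0h, 416 for dbko against wt at 0h, 545 for dbko against cko at 0h, 1075 for dbko against wt at 6h, 190 for dbko against cko at 6h, and 1290, 651 and 1 for the differences of response of cko from wt, dbko from wt and dbko from cko. With no filter on low counts it was 648 for cko against wt, 2361 for dbko against wt and 2124 for dbko against cko at 0h, 1030 for cko against wt at 6h, and 654 and 576 for the responses of cko against wt and dbko against cko. DESeq2 gave 385 for cko against wt at 0h and 494 and 252 for the same 2 differences of response. A replicate block within each genotype gave 344, 3046 and 2843 for cko against wt, dbko against wt and dbko against cko at 0h. It gave 588, 2685 and 329 for the responses in that order, and 2996 for dbko against cko at 6h. Without the second dbko replicates the numbers were 4717 and 4528 for dbko against wt and cko at 0h, 5647 and 4464 at 6h, and 4052 and 2080 for the responses, and without the first dbko replicates 288 for the response of dbko against cko. Apart from the settings that leave libraries out, the cause was not tested.

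Leaving out 1 library gave 4013 to 4152 called genes for wt at 6h against 0h, 4183 to 4368 for wt at 27h against 0h, 2100 to 2345 for wt at 27h against 6h, 3557 to 4518 for cko and 4509 to 5187 for dbko at 6h against 0h. At 0h it gave 38 to 48 for cko against wt, 445 to 3089 for dbko against wt and 227 to 3014 for dbko against cko, and at 6h 70 to 434, 1296 to 4210 and 559 to 3019. For the responses it gave 9 to 409 for cko against wt, 595 to 2638 for dbko against wt and 12 to 682 for dbko against cko.

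Among named genes, 1412 of 1426 results held with DESeq2 size factors, 1406 of 1426 with no filter, 1383 of 1422 with DESeq2, 1053 of 1409 with only the groups compared, 1398 of 1426 with a block within genotypes, 658 of 715 and 696 of 716 without the first and second dbko replicates, and 4774 of 6372 with 1 library left out. The replicate block ended 11 of 1426 and changed 7 list calls: erythroid markers in dbko at 6h against 0h (0.0534 to 0.00444), immunoglobulin constant genes in dbko against wt at 0h (0.0677 to 0.0392) and in the response of dbko against cko (0.0825 to 0.0431), genes next to Relb in dbko against wt at 0h (0.0168 to 0.0677) and against cko at 6h (0.0323 to 0.0968), and marginal zone markers in dbko against cko at 6h (0.0443 to 0.0766) and in the response of cko against wt (0.0585 to 0.0354). It changed no other list call. The simulation, with 200 changed genes and 1 dispersion per gene for all groups, called 11.1% of 1.5-fold and 82.8% of 4-fold changes. Comparisons with more changed genes have a less strict threshold.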

Other observations

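Among germinal centre markers 0 of 8 were higher and 3 lower (0 and 5 adjusted over the list alone) in cko against wt at 6h. Camera on the germinal centre list gave adjusted p = 1.84e-05, and adjusted p = 0.135 with an estimated correlation. In dbko against wt at 6h 0 of 8 were higher and 4 lower (0 and 5 adjusted over the list alone), with Bcl6, the repressor that sets up germinal centres, at -0.57. For the germinal centre list, camera gave adjusted p = 0.00773, and adjusted p = 0.287 with an estimated correlation. Among T cell markers 4 of 11 were higher and 0 lower (as many adjusted over the list alone) in dbko against wt at 6h. Camera on the T cell marker list gave adjusted p = 0.00286, and adjusted p = 0.268 with an estimated correlation. Transcripts of the mitochondrial genome fell in wt over 6h, as 0 of 12 rose and 9 fell (as many adjusted over the list alone). Camera on the mitochondrial list gave adjusted p = 0.00181, and adjusted p = 0.462 with an estimated correlation.

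Short lists gave counts alone. In dbko against wt at 0h, of the natural killer markers 0 of 4 were higher and 1 lower (1 and 1 adjusted over the list alone), of the neutrophil markers 2 of 4 were higher and 0 lower (4 and 0 adjusted over the list alone) and of the stromal and endothelial markers 0 of 3 were higher and 0 lower (as many adjusted over the list alone). Of the BAFF and APRIL receptors and ligands 3 of 3 rose and 0 fell (as many adjusted over the list alone) in dbko over 6h. Xist, the 1 sex-specific gene tested, rose by 1.42 in wt over 6h and by 1.75 over 27h. Its call over 6h ended without wt 0h replicate 1 (adjusted p = 0.0766), wt 0h replicate 2 (0.141) and wt 6h replicate 1 (0.122), and that over 27h without wt 0h replicate 2 (0.0743).

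Of the tests in this part, the one within 4 Mb of Relb was chosen after the result was seen and the others beforehand. Genes beside a targeted locus could differ between genotypes because DNA of another strain was carried along with the knockout. For Rel, 1 of 83 tested genes within 10 Mb was called in cko against wt at 0h and 187 of 12546 elsewhere, a ratio of 0.808 (95% interval 0.115 to 5.7, Fisher's exact p = 1.0), which leaves the question open. For Relb, 20 of 192 within 10 Mb were called in dbko against cko at 0h and 1119 of 12437 elsewhere. The ratio of 1.16 (0.762 to 1.76, Fisher's exact p = 0.448) leaves this open too, as few genes need differ. Within 4 Mb the ratio was 1.54 (9 of 65 against 1130 of 12564, 0.837 to 2.83, Fisher's exact p = 0.188), which leaves the nearest genes open, among them Apoe (-3.48) and Pglyrp1 (-2.15). Of the genes next to Rel, 1 of 13 were higher and 0 lower (as many adjusted over the list alone) in cko against wt at 0h, Ahsa2 at 1.04 being the 1 higher. Camera on the Rel neighbour list gave adjusted p = 0.442. At 6h 0 of 13 were higher and 1 lower (as many adjusted over the list alone). For the Rel neighbour list, camera gave adjusted p = 0.0301, and adjusted p = 0.384 with an estimated correlation. Of the genes next to Relb, 0 of 15 were higher and 2 lower (1 and 2 adjusted over the list alone) in dbko against wt at 0h, where camera placed the list lower, its median was -0.0634 and its mean 0.161. Camera on the Relb neighbour list gave adjusted p = 0.0168, and adjusted p = 0.512 with an estimated correlation. With the replicate block it was 0.0677. In dbko against wt at 6h 2 of 15 were higher and 1 lower (1 and 1 adjusted over the list alone), with a median of 0.0128. For the Relb neighbour list, camera gave adjusted p = 0.127. Between dbko and cko at 0h 0 of 15 were higher and 1 lower (1 and 1 adjusted over the list alone). The Relb neighbour list had a camera adjusted p = 0.254. Between dbko and cko at 6h, 0 of 15 were higher and 1 lower (as many adjusted over the list alone), where camera again placed it lower, with a median of -0.107 and a mean of 0.231. Camera on the Relb neighbour list gave adjusted p = 0.0323, and adjusted p = 0.526 with an estimated correlation. With the replicate block it was 0.0968.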
